A study of Mus musculus with 12 samples.

How the data were processed

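The data are RNA-seq of MIWI immunoprecipitates and of input RNA from mouse late spermatocytes, depleted of ribosomal RNA, with 2 samples in each of 6 groups per the labels. Per the labels' protocols, RNA was taken up in Trizol from testes or from sorted cells and libraries followed the standard Illumina procedure; which samples came from sorted cells is not given in the sources used here. TopHat, Bowtie and the mouse genome build mm9 are named per the submitters' processing notes, with no version, role or order. The counting tool and the gene annotation are not given in the sources used here.

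The deposited table gives RPKM, the reads of a gene per kilobase of its length and per 1000000 reads, as computed by the authors, in 6 columns for 20345 Ensembl gene IDs. Per the file headers the unit is written out for the Miwi +/- columns only. The other columns step in the same proportions for each gene, so their values are divided by gene length too. A column multiplied by a constant would step alike, so the same unit was assumed for them. Their read totals and the differences between genotypes rest on that. Column names give the group and no replicate number. Whether a column is 1 of the 2 samples or both pooled before RPKM was computed is not stated in the sources used here; a mean of the RPKM of libraries of different depth would not step in single reads. None of the IDs is at 0 in all columns. All 6 value columns were used.

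An RPKM value is a whole number of reads times a step set by the gene's length and the column's read total. The step of each gene was found as the largest unit of which its depth-scaled values are whole multiples, within 0.002 reads plus 1e-07 of the read number. All values (100%) of genes with a value in more than 1 column came out whole. For genes with values in 2 columns the search finds a fitting step by chance too, so this share does not show that their reads are right. For the 2893 genes with a value in 1 column only, that value was taken as 1 read. The read numbers of genes and the intervals of their ratios follow from the steps and the proportions between columns alone. Absolute read totals do not: a total smaller by a whole factor multiplies every length by it, and lengths then come out whole more often. The total of the Miwi ADH/- input was raised by factors of 2 and 3 from the smallest candidate for as long as the share of whole lengths fell by less than a bound chosen with these data in view. At 0.500 times the total used, the share was 0.633, but the listed genes would then hold 107% of a column's reads, which is more than its total if each read is counted once. Among the candidates that leave at most 100% in every column, the total used had the highest share, 0.520, against 0.316 for the next. Of 8744 genes under 2500 bases checked, 46.3% of lengths lay within 0.05 of a whole number, against 10% by chance, and 57.7% of doubled lengths did, as averages over transcripts would give. Were the totals off by a factor, the shares of reads in listed genes, the gene lengths and their classes, and values per 1000000 reads would change with it, while RPKM, log2 differences, read numbers of genes and ratio intervals would not. On simulated tables with known reads, all reads were right for 96.6% of 12614 genes that pass the filter below and for 88.4% of all 19189 genes.

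The tests fixed before the data were examined were models across replicate libraries. They could not be run on 1 RPKM column per group, so each comparison is a difference of log2(RPKM + 1), with a pseudocount of 1, between the columns concerned: IP minus input in each genotype, the difference of these between genotypes (IP enrichment), and the inputs against each other. A log2 difference on this scale understates the change of genes near or below 1 RPKM. The 12246 genes with at least 1 RPKM in at least 2 columns were kept, and differences of at least 2-fold were counted. This is a count by size, not a test. The counts were also taken relative to the median difference of all kept genes, because IP and input columns differ in the share of their reads in listed genes. Ratios of reads have exact 95% intervals (Clopper-Pearson, conditional on the summed reads), which compare these libraries and not the conditions, and cover counting error only, since PCR copies are not independent molecules.

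On simulated inputs with 50 genes per fold size, drawn from the real read numbers, the count took in 86% of genes changed 4-fold, 32% of those changed 2-fold and 0.812% of 11817 unchanged genes for Miwi ADH/- against Miwi +/-, out of 12017 genes. For Miwi -/- against Miwi +/- these were 92%, 26% and 0.542%, out of 12017 genes, and for Miwi ADH/- against Miwi -/- 88%, 26% and 0.930% of 11501, out of 11701.

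The rule for named genes, fixed beforehand, asked for genes with a symbol, past the test, with a mean log2 CPM at or above the median of the kept genes. It also asked that every library of one group lie beyond every library of the other. The targeted gene was to be given in every comparison, with more genes per direction than here and members of the fixed lists. With no symbols and no test, the part on the test was replaced, after the data were seen, by a counting interval that excludes equality, or for IP enrichment by intervals of the genotypes' IP-to-input ratios that do not overlap, and the 2 largest differences in each direction were named. A level at or above the median was met by 6123 genes. A reference gene table of the assembly GRCm38.p6 with 49997 rows was searched for names; 0 rows carry an Ensembl ID and 0 of the IDs matched. Gene lists for 19 pathways and cell types were fixed beforehand and are not analysed here for that reason.

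Genes were grouped by recovered length, a choice made after seeing the data, and the median of each class was placed among 10000 random lists of equal size drawn from the same expression levels. Overlaps between comparisons that share a column are given beside the number for independent lists and beside the mean of 20 simulations in which every column is drawn from the shared control with counting noise. In an alternative added after seeing the data, the reads of the shared control were split at random, with 1 part for each comparison, in 20 draws; this removes shared counting noise only. Alternatives were pseudocounts of 0.1 and 5, no filter on low values, a mean of at least 50 reads, median-of-ratios and upper quartile scaling and a direct comparison of IP columns; equal column totals and leaving out genes under 300 bases were added after seeing the data. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.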

Results

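MIWI is the mouse PIWI-clade Argonaute protein that binds pachytene piRNAs, the small RNAs that accumulate in meiotic and early post-meiotic male germ cells. RNA that co-purified with MIWI and the RNA of the starting material (input) were sequenced after removal of ribosomal RNA, in late spermatocytes of 3 genotypes: Miwi +/-, Miwi -/- and Miwi ADH/-. The ADH allele is known from earlier work as a mutant of the catalytic site with which PIWI proteins cut their target RNAs, so in Miwi ADH/- animals the only remaining copy carries that mutation. The comparisons address which RNAs are recovered with MIWI and how much of that recovery depends on the protein and on its catalytic site. They also address how the input RNA differs between the genotypes. The Miwi -/- immunoprecipitation (IP) is the background control of the antibody.

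The labels describe 12 samples, 2 for each of the 6 combinations of genotype and IP or input. The values used here are 1 column of RPKM (reads per kilobase of gene length and per 1000000 reads) per combination, for 20345 Ensembl genes, so no replicate values were at hand. Each difference below is between single columns, has no replicate check and carries no p-value, and the intervals given cover counting error of the reads only. Genes are counted as higher or lower where they were at least 2-fold apart on the log2(RPKM + 1) scale, among 12246 genes with at least 1 RPKM in at least 2 columns.

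Read numbers differed between the columns. The RPKM values of each gene step in units of 1 read. Read totals follow from the steps only up to a common factor, which was set from the lengths coming out whole. The totals, the shares of reads in listed genes and the gene lengths below depend on it, while reads per gene and counting intervals do not. The totals were 5887878 for the Miwi +/- IP, 10581235 for the Miwi ADH/- IP and 4172542 for the Miwi -/- IP. The inputs had 7491513 (Miwi +/-), 5488633 (Miwi ADH/-) and 7102637 reads (Miwi -/-). The listed genes held 29.3%, 35.0% and 18.3% of the reads of the Miwi +/-, ADH/- and -/- IPs, against 52.3%, 47.9% and 53.7% of those of the inputs. In reads, the listed genes held 1725558, 3706479 and 761525 in the IPs and 3918947, 2627634 and 3810918 in the inputs, in the same order. The Miwi -/- IP was thus the shallowest column, and 3 reads in a gene of 1000 bases were worth 0.719 RPKM there, against 0.284 RPKM in the Miwi ADH/- IP. It had the fewest genes with at least 1 RPKM (7305, against 9942 and 10530 in the Miwi +/- and ADH/- IPs and 10912 to 11602 in the inputs). The 10 most-read genes took 8.88% of its listed reads, against 4.45% to 5.37% in the other columns.

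**Figure D1:**
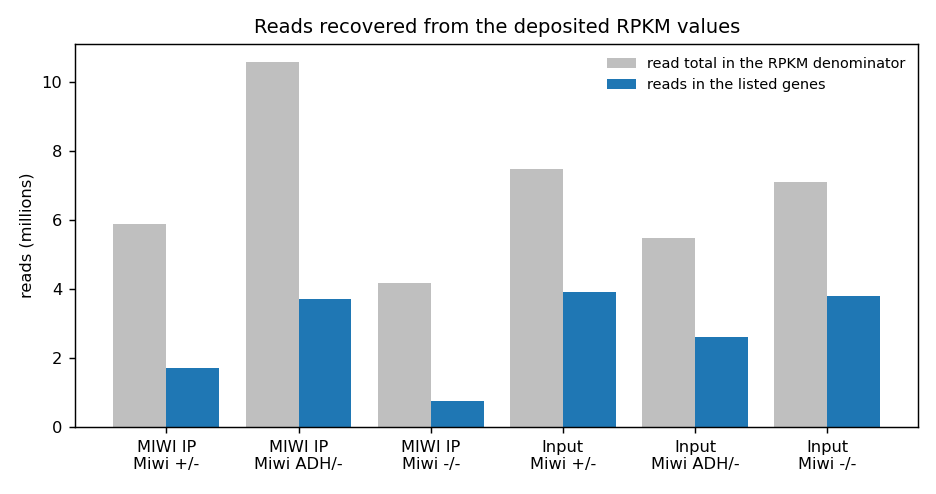
Reads (axis in units of 1000000) for the 6 columns, as recovered from the deposited values: grey bars give the read total in the RPKM denominator and blue bars the reads in the listed genes. The Miwi -/- IP has the lowest bars of both kinds, 4172542 and 761525 reads.

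Genes are given by their Ensembl IDs. The table does not pair the IDs with names, and the reference gene table used here matched 0 of them, so at most 2 IDs that were higher and 2 that were lower are named per comparison. For the same reason the level of the targeted gene in each column, which would check the genotype labels, is not reported here, and the pathway and cell-type lists fixed beforehand gave no values. Groups of genes are described by length, which the RPKM steps also gave.

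In the Miwi +/- cells, IP-minus-input values rose with gene length from 300 bases upwards. On the deposited scale the median log2 difference was -0.99 for the 342 genes under 300 bases, -1.09 for the 2739 genes of 300 to under 1000 bases, -0.82 for the 4546 genes of 1000 to under 2000 bases, -0.63 for the 3606 genes of 2000 to under 4000 bases and -0.42 for the 1013 genes of 4000 bases and more. The last 2 classes lay above all of 10000 random gene lists of equal size and expression, and the class of 300 to under 1000 bases lay below all of them. In all, 519 genes were higher in the IP and 4976 were lower, with counting intervals excluding equality for 498 and 4826 of them. ENSMUSG00000080860 had 129.9 RPKM in the IP and 12.6 in the input, a 10.3-fold difference with a 95% counting interval of 7.35 to 14.7. ENSMUSG00000011382 had 10.3 RPKM against 0.240, a 42.9-fold difference with an interval of 16.4 to 160 that rests on 4 input reads. On the other side, ENSMUSG00000081051 was 73.5-fold lower in the IP (20.1 to 611, from 2 IP reads) and ENSMUSG00000042670 52.5-fold lower (20.3 to 194, from 4 IP reads). The balance of higher and lower genes, and which length class lies nearest to its input, depend on the scale: relative to the median of all genes, those of 1000 to under 2000 bases lay at -0.05 and those of 4000 bases and more at 0.35. The median log2 difference of all genes was -0.77, 1890 genes were higher and 1894 lower relative to it, and median-of-ratios scaling gave 1609 and 2123.

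The Miwi ADH/- IP followed its input more closely than the Miwi +/- IP did, and the order of the length classes was similar. Medians were -0.67 for genes under 300 bases, -0.77 for genes of 300 to under 1000 bases, -0.44 and -0.25 for the next longer classes and -0.12 for genes of 4000 bases and more. There were 591 genes higher in the IP and 3057 lower, with counting intervals excluding equality for 557 and 2968. ENSMUSG00000029423 had 319.7 RPKM in the IP and 50.3 in the input, a 6.35-fold difference (5.97 to 6.77) based on 13340 IP reads. The same gene stood at 199 RPKM in the IP and 49.2 in the input of Miwi +/-, and at 4.50 and 6.71 RPKM in those of Miwi -/-. ENSMUSG00000085210 had 21.2 RPKM in the IP and 2.30 in the input, a 9.20-fold difference (6.71 to 12.9). ENSMUSG00000088529, of 193 bases, was 24.0-fold lower in the IP (13.0 to 49.2) and ENSMUSG00000063696 was 22.6-fold lower (14.3 to 37.6). With the median difference of -0.41 as the reference, 1472 genes were higher and 1640 lower, median-of-ratios scaling gave 1208 and 1765, and equal column totals turned the balance to 1621 higher and 1402 lower.

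In the Miwi -/- background control, the IP departed furthest from its input: 449 genes were higher in the IP and 7463 lower, with counting intervals excluding equality for 425 and 7215. ENSMUSG00000085210 had 70.7 RPKM in this IP against 1.78 in the input, 39.7-fold higher (29.1 to 55.7), which is above its 26.0 and 21.2 RPKM in the Miwi +/- and ADH/- IPs. ENSMUSG00000075014 was 24.6-fold higher (18.0 to 34.5), at 220.4 RPKM here, against 19.3 and 14.5 in the Miwi +/- and ADH/- IPs. The lowest were ENSMUSG00000021606 and ENSMUSG00000044424, at 185 and 118 RPKM in the input, with 2 and 1 reads in the IP. Their input-to-IP ratios were 239 (66.0 to 1978) and 286 (51.0 to 11299.8). Class medians ran from -1.69 for genes of 300 to under 1000 bases to -0.99 for genes of 4000 bases and more, with -1.36 for those under 300 bases. Against the median difference of -1.37, 2885 genes were higher and 3066 lower, and median-of-ratios scaling gave 2532 and 3823.

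Across genes, which are not independent replicates, the correlation of log2 values between IP and own input was 0.846 in Miwi +/-, 0.881 in Miwi ADH/- and 0.731 in Miwi -/-. The genes higher in the IP overlapped between genotypes, the control included. Of the 519 genes in Miwi +/- and the 591 in Miwi ADH/-, 160 were shared, against 25.05 for independent lists. Miwi +/- shared 113 with the Miwi -/- control (19.0 for independent lists), and Miwi ADH/- shared 131 with it (21.7). In all 3 genotypes 73 genes were higher in the IP, and 87 were higher in Miwi +/- and ADH/- without being so in Miwi -/-.

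**Figure D2:**
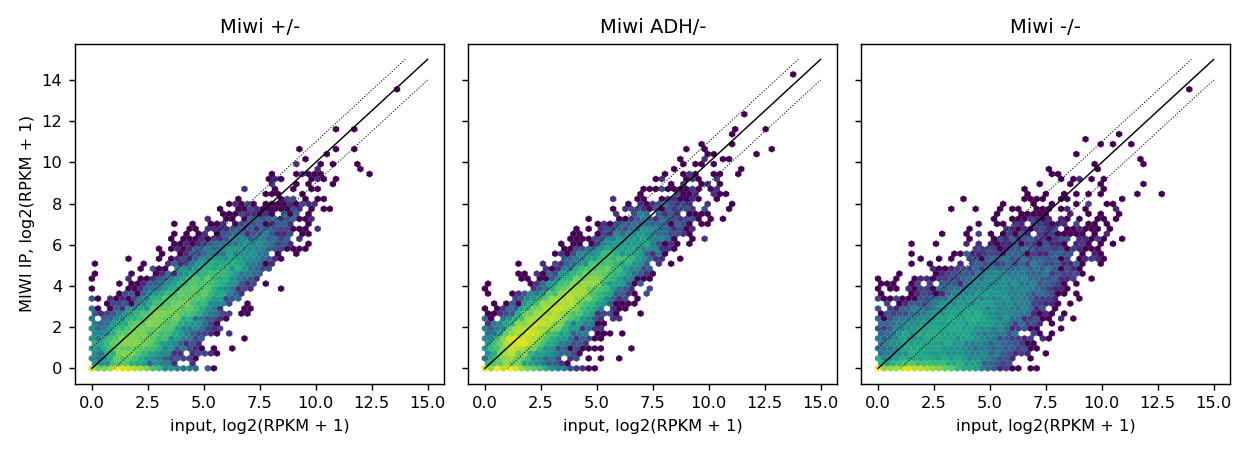
MIWI IP against input, log2(RPKM + 1), for the 12246 genes in each genotype; colour gives the number of genes per hexagon on a log scale, the solid line equality and the dotted lines a 2-fold difference. The cloud is widest and lies furthest below the line in Miwi -/- (correlation 0.731), and is narrowest in Miwi ADH/- (0.881).

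Enrichment over the control asks which RNAs stood higher in the IP, relative to input, than where MIWI is absent. In Miwi +/-, 4815 genes were higher than in Miwi -/- by this measure and 1171 lower. ENSMUSG00000086161 had an IP-to-input ratio of 3.88 (2.99 to 5.10) in Miwi +/- and of 0.0695 (0.0469 to 0.0995) in Miwi -/-, a log2 difference of 5.62. ENSMUSG00000082396 had ratios of 5.24 (4.11 to 6.76) and 0.0880 (0.0396 to 0.171), a log2 difference of 5.47. Between the IP columns alone the differences were 2.31 and 4.36, and the rest comes from higher Miwi -/- inputs. In the opposite direction stood ENSMUSG00000022501, with ratios of 0.0419 and 9.08 and a log2 difference of -6.75, and ENSMUSG00000026182, with 0.156 and 10.6 and -5.38. These rest on 3 and 4 reads in the Miwi -/- input, in that order, and both genes had more RPKM in the Miwi +/- IP (14.1 and 104) than in the Miwi -/- IP (8.18 and 14.3). Of the 519 genes higher in the Miwi +/- IP than in its input, 354 (68.2%) were also at least 2-fold above the control by this measure, against 39.3% of all genes; both measures hold the same IP and input values, which raises the first share. The shortest genes, the 342 under 300 bases, had a median difference of 0.22 against 0.60 to 0.74 in the longer classes. Relative to the median of 0.67 over all genes, 2617 were higher and 2466 lower, and median-of-ratios scaling gave 3261 and 2377.

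The Miwi ADH/- IP stood above the control in more genes on this scale, 6357 higher and 894 lower. ENSMUSG00000035674 had an IP-to-input ratio of 1.02 (0.925 to 1.13) in Miwi ADH/- and of 0.0104 (0.00419 to 0.0216) in Miwi -/-, a log2 difference of 6.30. ENSMUSG00000068851 had ratios of 3.34 (2.37 to 4.84) and 0.0309 (0.00370 to 0.114, from 2 IP reads), a log2 difference of 6.02. ENSMUSG00000026182 and ENSMUSG00000022501 were again the lowest, at log2 differences of -5.83 and -5.64. Of the 591 genes higher in the Miwi ADH/- IP than in its input, 372 (62.9%) were at least 2-fold above the control, against 51.9% of all genes, with the same reservation. Of these, 67 were among the 354 of Miwi +/-, against 10.8 for independent lists. Simulated columns without differences that share the control gave lists of 16.15 and 17.05 genes on average with 4.80 shared, a larger part of much shorter lists, so sharing the control alone raises the overlap. With the control reads split between the genotypes, a mean of 63.4 were shared, against 10.7 for independent lists. Measured from the median of 1.06, 2463 genes were higher and 2655 lower, and median-of-ratios scaling gave 3355 and 2410.

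These enrichments share the Miwi -/- columns, which adds agreement by chance. Both were higher for 4067 genes and both lower for 535, with 97 in opposite directions. Independent lists would give 2499.5 and 85.5. Simulated columns without differences, sharing the control, gave means of 34.5 and 29.4 over 20 draws. Those columns differ by counting noise only, so these means are no scale for the overlap of the observed lists. Relative to each comparison's median, both were higher for 1660 genes (526 for independent lists) and both lower for 1612 (535). The correlation of the log2 differences across genes was 0.745, and the shared control alone gave 0.559 in the simulation without differences. Their covariance was 1.36, against 0.0703 in the simulation with counting noise alone, a difference of 1.29. With the control reads split at random between the comparisons, means of 3936 and 505 genes were both higher and both lower, against 2505 and 92.1 for independent lists, and the covariance was 1.29. That split removes shared counting noise only. Both enrichments subtract the same IP-minus-input values of Miwi -/-. The standard deviation of these values across genes was 1.42, against 1.35 for each enrichment. The control columns cannot be split by library, so part or all of the excess may come from them.

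Set against each other, the Miwi ADH/- IP was the more enriched for 2509 genes and the less enriched for 926. ENSMUSG00000087935, of 178 bases, had an IP-to-input ratio of 1.51 (1.03 to 2.26) in Miwi ADH/- and of 0.0785 (0.0248 to 0.191) in Miwi +/-, a log2 difference of 4.01. ENSMUSG00000078442 had ratios of 0.887 (0.695 to 1.14) and 0.0535 (0.0241 to 0.104), a log2 difference of 3.06. The other way, ENSMUSG00000011382 had 1.51 (1.11 to 2.08) and 42.9 (16.4 to 160), a log2 difference of -2.69, and ENSMUSG00000086161 had 0.709 (0.659 to 0.763) and 3.88 (2.99 to 5.10), a log2 difference of -2.39. For ENSMUSG00000086161 the IP level itself was higher in Miwi ADH/-, at 246 RPKM against 59.2, and its input level differed more, as described next. The excess of higher genes depends on the scale: measured from the median of 0.38, 1303 genes were higher and 1642 lower, median-of-ratios scaling gave 1471 and 1460, and equal column totals gave 1814 and 1290.

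The inputs give the RNA of the starting material. The sources used here do not say which samples came from testes and which from sorted cells. A difference in cell mixture between the inputs was not tested. Between Miwi ADH/- and Miwi +/-, 955 genes were higher in the mutant and 909 lower, with counting intervals excluding equality for 870 and 843. ENSMUSG00000086161 had 347 RPKM in Miwi ADH/- and 15.2 in Miwi +/-, 22.8-fold higher (18.0 to 29.1), and ENSMUSG00000021078 had 127 against 14.8, 8.58-fold higher (6.61 to 11.3). ENSMUSG00000049539 was 4.54-fold lower (3.64 to 5.72), at 22.4 RPKM against 102, and ENSMUSG00000028851 was 3.83-fold lower (2.94 to 5.05), at 16.9 against 64.9. Genes of 300 to under 1000 bases lay highest: relative to the median of all genes, these 2739 genes were 0.30 higher on the log2 scale, above all of 10000 random lists, while those of 2000 to under 4000 bases lay at -0.12 and those of 4000 bases and more at -0.10, below all of them. The 342 genes under 300 bases lay at 0.08, the 91.7th percentile, with 75 higher and 72 lower. Of the genes of 300 to under 1000 bases, 470 were higher and 211 lower, against 21 and 26 of the 1013 longest. Relative to the median of -0.16, 1273 genes were higher and 546 lower, median-of-ratios scaling gave 1111 and 356, and equal column totals gave 721 and 824, so the balance depends on the scale.

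Between Miwi -/- and Miwi +/-, more genes were lower in the mutant input than higher, 1295 against 547, with counting intervals excluding equality for 1222 and 485. The lowest are named among genes at or above the median level only. ENSMUSG00000026182 had 671 RPKM in Miwi +/- and 1.35 in Miwi -/-, 498-fold lower (194 to 1829, from 4 reads), and ENSMUSG00000022501 had 337 against 0.901, 374-fold lower (128 to 1817, from 3 reads). In Miwi ADH/- the same transcripts stood at 2296 and 900.1 RPKM. A group of 175 genes was at least 8-fold lower in the Miwi -/- input, with a median length of 764 bases and a median level of 0.479 RPKM, against 21.2 in Miwi +/- and 29.6 in Miwi ADH/-. Higher in Miwi -/- were ENSMUSG00000086161, at 160.5 RPKM (10.5-fold, 8.31 to 13.5), and ENSMUSG00000006906, at 87.4 RPKM against 10.3 (8.51-fold, 7.24 to 10.1). The medians of the length classes lay between -0.03 and 0.02, with that of the longest genes at the 99.98th percentile of random lists, and shorter genes were counted more often in both directions: 17.7% of the genes of 300 to under 1000 bases were lower and 7.92% higher, against 3.16% and 1.38% of the longest. Relative to the median of -0.02, 566 genes were higher and 1267 lower.

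The mutant inputs differed from each other in more genes than either did from Miwi +/-: 1537 were higher in Miwi ADH/- than in Miwi -/- and 801 lower, with counting intervals excluding equality for 1443 and 715. ENSMUSG00000026182 and ENSMUSG00000022501 led the higher genes, at log2 differences of 9.93 and 8.89. ENSMUSG00000018593 was 5.85-fold lower in Miwi ADH/- (4.33 to 8.05), at 7.04 RPKM against 41.2, and ENSMUSG00000022037 was 5.17-fold lower (3.87 to 7.01), at 11.1 against 57.2. Measured from the median of -0.18, 1814 genes were higher and 453 lower, and median-of-ratios scaling gave 1528 and 381.

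Both mutant inputs were higher than the Miwi +/- input for 229 genes, ENSMUSG00000086161 among them, and both lower for 155, while 240 went in opposite directions. Independent lists would give 42.7 and 96.1, and simulated unchanged inputs set against the shared Miwi +/- column gave means of 15.1 and 8.80. Such inputs differ by counting noise only, so the simulated means are no scale for the overlap of the observed lists. The correlation of the log2 differences across genes was 0.107, and the shared column alone gave 0.460 in the simulation without differences. Their covariance was 0.0688 against 0.0287 simulated, a difference of 0.0401. Relative to each comparison's median, both were higher for 287 genes (58.8 for independent lists) and both lower for 103 (56.5), with 288 in opposite directions. With the Miwi +/- reads split at random between the comparisons, means of 225 and 140.0 genes were both higher and both lower, against 52.4 and 100.1 for independent lists, 279 went in opposite directions, and the covariance was 0.0400. The column cannot be split by library, so part or all of the excess may still come from it.

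**Figure D3:**
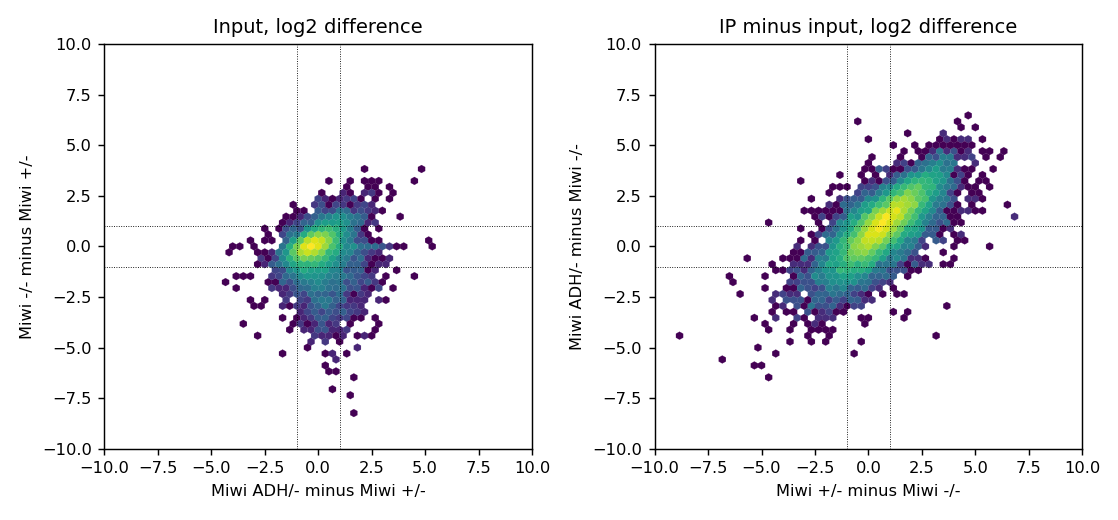
Log2 differences of the 12246 genes in comparisons that share columns; colour gives the number of genes per hexagon on a log scale and dotted lines mark 2-fold differences. The inputs of both mutants against Miwi +/- (left, correlation 0.107) show a tail of genes lower in Miwi -/- and not in Miwi ADH/-. The IP enrichments over Miwi -/- (right) have a correlation of 0.745. Simulated columns without differences that share the control gave 0.460 (left) and 0.559 (right). They differ by counting noise only, so these values are no scale for the observed correlations.

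**Figure D4:**
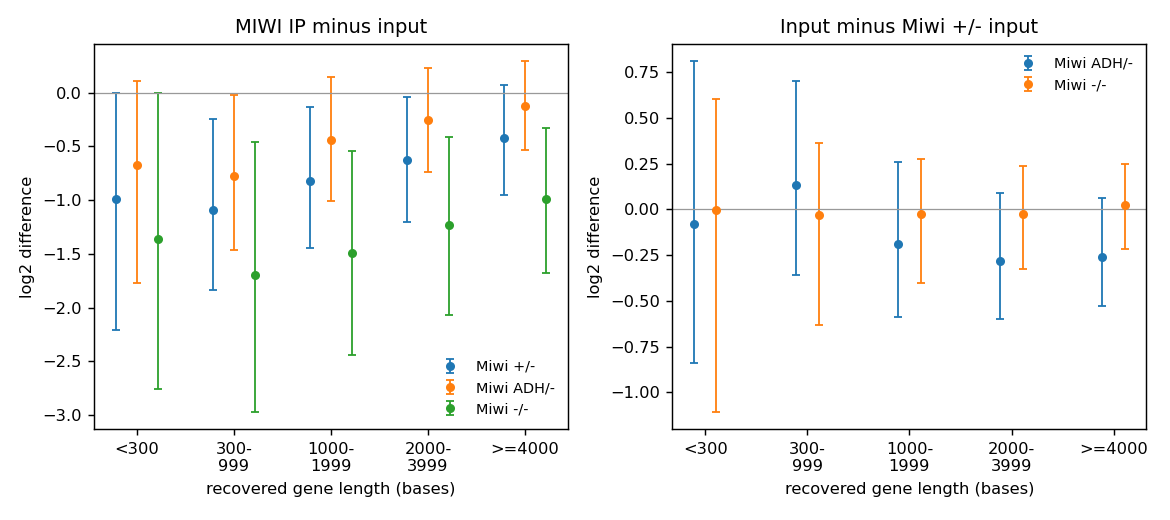
Median log2 difference by length class of the genes, with bars from the lower to the upper quartile of the genes in each class: IP minus input in each genotype (left) and mutant inputs minus the Miwi +/- input (right). From 300 bases upwards, the medians rise with length in all 3 IPs, and genes of 300 to under 1000 bases lie highest in the Miwi ADH/- input.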

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

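Among the named genes, 6 were at least 2-fold higher in the IP than in the input in one genotype and at least 2-fold lower in another. With 1 column per group, the difference was not tested for any of them. IP-minus-input values are on the log2(RPKM + 1) scale. The tests of a fixed share of reads carried over, below, were chosen only after the result was seen.

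ENSMUSG00000086161 stood at 1.89 in Miwi +/-, -0.50 in Miwi ADH/- and -3.73 in Miwi -/-, a span of 5.62. ENSMUSG00000082396 stood at 2.32, 1.09 and -3.15, a span of 5.47, and ENSMUSG00000006906 at 1.21, -0.26 and -2.21, a span of 3.42. Between Miwi -/- and Miwi +/-, the inputs alone differed by 3.31, 1.12 and 2.97 for these genes, in the same order, which is most of the span of ENSMUSG00000086161 and ENSMUSG00000006906. The IP levels of ENSMUSG00000006906 were close, at 18.1 and 25.04 RPKM. ENSMUSG00000068851 stood at -0.10, 1.70 and -4.32, a span of 6.02 that rests on 2 reads in the Miwi -/- IP.

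ENSMUSG00000022501 and ENSMUSG00000026182 went the other way: -4.48, -3.37 and 2.27 for the first (a span of 6.75 between Miwi -/- and Miwi +/-) and -2.67, -3.12 and 2.71 for the second (a span of 5.83 between Miwi -/- and Miwi ADH/-). They belong to the 175 genes at least 8-fold lower in the Miwi -/- input than in the Miwi +/- input. Summed over these genes, the IP-to-input ratio was 0.301 in both Miwi +/- and Miwi ADH/-, below the other genes' 0.563 and 0.739, but 0.786 (0.705 to 0.874) in Miwi -/-, above the other genes' 0.340. Gene by gene in Miwi -/-, 17 were at least 2-fold higher in the IP and 21 at least 2-fold lower, with a median log2 difference of 0. Their median levels there were 0.333 RPKM in the IP and 0.479 in the input, where this scale understates differences.

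Choosing genes by a low input biases their ratio upwards, so the set was chosen again on a random part of the Miwi -/- input reads and measured on the remaining reads. In a single random split, the ratio was then 0.713 (0.635 to 0.801) for 189 genes, against 0.340 for the others. The criterion set beforehand asked for the interval to lie above 0.680. The ratio passed that bound but its lower limit did not, so the criterion was not met. The interval does lie above the 0.340 of the other genes, which argues against the choice by low input as the whole cause. Those genes were not matched for level, so low read numbers as such are not ruled out. Carry-over of a fixed share of another library into the Miwi -/- IP cannot be told apart from other sources: only 1.22% of 1878 other genes with at least 500 Miwi +/- input reads fell below the set's share of 1.44%, and 1.24% of 1691 genes fell below its 2.02% share of the Miwi ADH/- IP. The set's own genes did not hold a single share. For its 118 genes with at least 100 Miwi +/- input reads, the quartiles of the share were 0.469% and 1.45%. For its 80 genes with at least 100 Miwi ADH/- IP reads they were 0.589% and 2.16%. The summed shares thus lie close to the upper quartiles, and a smaller fixed share was not tested. Most other abundant genes have far more Miwi -/- IP reads than such a share would bring, and their own RNA could give these reads without carry-over. The comparison could thus hardly count against carry-over, which stays open, and gives it no support. No biological explanation was tested, and a difference between genotypes stays open too.

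The lower correlation of the Miwi -/- IP with its input was set against its depth. With all columns thinned to 761525 listed reads, the correlations averaged 0.829 in Miwi +/-, 0.861 in Miwi ADH/- and 0.723 in Miwi -/- over 20 draws. The smallest gap between Miwi -/- and the nearer of the others was 0.103, above the bound of 0.02 set beforehand, which argues against read number as the whole cause. Loss of the protein the antibody binds, or a lower yield of the precipitation, may lie behind the gap; with 1 column per group neither was tested.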

How the results depend on the processing

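Of 150 recomputed counts of higher or lower genes, 69 stayed within 1.5 times the reported count and 81 moved further. Leaving out the genes under 300 bases moved none by that much. Pseudocounts and filters change the counts by construction, as they shrink or widen the differences of low genes or the number of genes kept; for the scalings the shift of the median is given with each comparison, and no other cause was tested. A pseudocount of 0.1 gave 841 higher for the +/- IP against its input, 991 higher for the ADH/- IP against its input, and 695 higher for the -/- IP against its input. In the same setting, there were 1523 lower for the enrichment of ADH/- over +/-, 1642 lower for the ADH/- against the +/- input, and 977 higher for the -/- against the +/- input. It also left 1506 lower for the ADH/- against the -/- input. With a pseudocount of 5 the counts were 169 higher and 2574 lower for the +/- IP against its input, 184 higher and 1529 lower for the ADH/- IP against its input, and 155 higher and 4498 lower for the -/- IP against its input. In the same setting, there were 2198 higher and 377 lower for the enrichment of +/- over -/-, 3356 higher and 347 lower for the enrichment of ADH/- over -/-, and 704 higher and 241 lower for the enrichment of ADH/- over +/-. It also left 308 higher and 144 lower for the ADH/- against the +/- input, 114 higher and 446 lower for the -/- against the +/- input, and 695 higher and 113 lower for the ADH/- against the -/- input. Restricting the genes to those with a mean of at least 50 reads left 199 higher and 3108 lower for the +/- IP against its input, 316 higher and 1758 lower for the ADH/- IP against its input, and 167 higher and 4915 lower for the -/- IP against its input. In the same setting, there were 3190 higher and 309 lower for the enrichment of +/- over -/-, 194 lower for the enrichment of ADH/- over -/-, and 1256 higher and 187 lower for the enrichment of ADH/- over +/-. It also left 245 higher and 330 lower for the ADH/- against the +/- input, 132 higher and 435 lower for the -/- against the +/- input, and 505 higher and 248 lower for the ADH/- against the -/- input. Median-of-ratios scaling gave 1609 higher and 2123 lower for the +/- IP against its input, 1208 higher and 1765 lower for the ADH/- IP against its input, and 2532 higher and 3823 lower for the -/- IP against its input. In the same setting, there were 2377 lower for the enrichment of +/- over -/-, 3355 higher and 2410 lower for the enrichment of ADH/- over -/-, and 1471 higher and 1460 lower for the enrichment of ADH/- over +/-. It also left 356 lower for the ADH/- against the +/- input, and 381 lower for the ADH/- against the -/- input. Under upper quartile scaling there were 1756 higher and 2033 lower for the +/- IP against its input, 1376 higher and 1580 lower for the ADH/- IP against its input, and 2471 higher and 3894 lower for the -/- IP against its input. In the same setting, there were 2209 lower for the enrichment of +/- over -/-, 3582 higher and 2159 lower for the enrichment of ADH/- over -/-, and 1558 higher and 1427 lower for the enrichment of ADH/- over +/-. It also left 459 lower for the ADH/- against the +/- input, and 462 lower for the ADH/- against the -/- input. Scaling each column to an equal total RPKM gave 1753 higher and 2153 lower for the +/- IP against its input, 1621 higher and 1402 lower for the ADH/- IP against its input, and 2019 higher and 4297 lower for the -/- IP against its input. In the same setting, there were 1831 lower for the enrichment of +/- over -/-, and 4231 higher and 1620 lower for the enrichment of ADH/- over -/-. Without the low-value filter there were 730 higher for the -/- IP against its input, 1522 lower for the enrichment of ADH/- over -/-, and 1489 lower for the enrichment of ADH/- over +/-. Comparing the IP columns directly, without the inputs, gave 657 lower for the enrichment of +/- over -/-. For the 36 named results, settings that only choose the genes kept cannot change a gene's difference, which fixes 106 of 298 recomputed values. Of the other 192, 186 kept their direction and a 2-fold size. The exceptions all came from comparing IP columns without their inputs, where the input difference of the gene no longer enters; of the 12 results recomputed that way, 6 kept both. ENSMUSG00000022501 then stood at 0.72 in Miwi +/- over Miwi -/- and at 3.25 in Miwi ADH/- over Miwi -/-, and ENSMUSG00000026182 at 2.78 and 4.10, all reversed. ENSMUSG00000086161 was reversed in Miwi ADH/- over Miwi +/-, at 2.04, and ENSMUSG00000011382 kept its direction there at -0.51. No paired analysis was possible because the columns carry no replicate number and there is 1 per group. For the same reason the count models, the weighted linear model, the replicate block, leaving out each library, the fit of only the compared groups and the gene list tests were not run; scaling by library size alone is the deposited scale, and TMM factors were not run. Depth limits the Miwi -/- IP most, with 761525 reads in listed genes.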

Other observations

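Genes of 300 to under 1000 bases stood higher in the Miwi ADH/- than in the Miwi +/- material, relative to long genes, in input and IP alike. In the inputs, the median log2 difference of these 2739 genes lay 0.41 (bootstrap interval 0.38 to 0.45) above that of the 4619 genes of 2000 bases and more, and between the IPs 0.34 (0.28 to 0.40) above it. The 342 genes under 300 bases lay 0.20 (0.03 to 0.29) above the long genes in the inputs and at -0.13 (-0.15 to -0.10) in the IPs. Genes without reads in both IPs give a difference of exactly 0, so the IP value may reflect missing reads and does not show an absent shift. For all genes under 1000 bases, 3081 in number, the contrast was 0.40 (0.36 to 0.43) in the inputs and 0.30 (0.24 to 0.36) in the IPs, and between the Miwi -/- and Miwi +/- inputs it was -0.01 (-0.05 to 0.01). The intervals cover the choice of genes and not differences between libraries.

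The shift of all genes under 1000 bases was tested against explanations written before the tests were run. Without the genes at least 2-fold apart between the Miwi -/- and Miwi +/- inputs it was 0.36 (0.32 to 0.39), so those genes do not account for it. With at least 100 reads in both inputs and no pseudocount it was 0.45 (0.40 to 0.49), which argues against counting noise of short genes at the pseudocount. RNA integrity, fragment size and library preparation may differ between these columns and were not tested, and neither was a change in cell stage; the cell-type lists fixed beforehand had no names to match.

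The 175 genes at least 8-fold lower in the Miwi -/- input were more abundant in Miwi ADH/- than in Miwi +/-: per 1000000 reads they took 7824 in the Miwi ADH/- input, 4669.8 in Miwi +/- and 153 in Miwi -/-. In the IPs they took 2359, 1404 and 121, in the same order. Their median length was 764 bases, and genes of 300 to under 1000 bases as a whole stood higher in Miwi ADH/- too, relative to long genes. That shift was not separated from the rise of the set. In 134 of the 175 genes the Miwi +/- IP was at least 2-fold below its input, and in 0 at least 2-fold above it, against 4976 and 519 of the 12246 genes tested. Choosing genes with more Miwi +/- than Miwi -/- input favours a low Miwi +/- ratio. In Miwi ADH/-, whose columns took no part in the choice, the IP was at least 2-fold below its input in 133 of the 175 and above it in 1, against 3057 and 591 of all. Among the 2739 genes of 300 to under 1000 bases these numbers were 1147 and 139. The set was not compared with genes matched for length and level.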
